A study of Arabidopsis thaliana and Setaria viridis and Zea mays with 22 samples.

How the data were processed

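Protoplasts and nuclei from root tips of Arabidopsis (Col-0), maize, sorghum and Setaria were run on the 10x Chromium 3' kit. Per the labels, tips were taken at 150 µm in Arabidopsis, 0.5 cm in maize and sorghum and 0.2 cm in Setaria, after 7 days of growth (15 days in Setaria). The age tag of every sample says 10 days, which differs from these growth times. Per the labels, chemistry version 2 was used for all Arabidopsis protoplasts, maize nuclei, sorghum protoplasts and Setaria protoplast replicate 1, and version 3 for the rest.

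The deposited tables hold 1 entry per cell, with counts of UMIs and of detected genes per cell, the library, the cluster and, for Arabidopsis, a cell type name given by the authors. The counts are not normalized. The submitters' processing notes name Cell Ranger 5.0.1, Seurat 4.0 and the build TAIR10. Per the file headers, libraries were integrated and clustered at resolution 0.6, separately for Arabidopsis and for the grasses, so no value is compared between those sets. The filters on cells, the treatment of doublets and the grass genome builds are not given in the sources used here. The tables themselves show that Arabidopsis protoplasts begin at 10002 UMIs or more and Arabidopsis nuclei at 1001 genes, so the preparations begin at different minima. Names such as 16_Undertermided are spelled as deposited.

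There are 33875 entries for Arabidopsis and 47536 for the grasses. In the Arabidopsis library ical1 each of the 1085 cells was listed 2 times with equal UMIs and genes, and the first listing was kept. From the grass table, 3 maize protoplast libraries with 4324 cells belong to another study and were not used. Libraries were assigned to groups by species and preparation. The 6 Arabidopsis protoplast libraries (ctr1, ctr3248V3, ctr4h, ctr914, ical1, ical32hV3) and the 3 sorghum nuclei libraries (Sorgh_Nucl, Sorgh_Nucl1, Sorgh_Nucl2) carry names that match no replicate number and are called by those names, whose meaning is not given in the sources used here. Setaria protoplast replicate 1 was assigned by elimination.

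Libraries held 113 to 8551 cells. Total UMIs per library ran from 50723576 to 138202792 in Arabidopsis protoplasts, 16761417 to 23093915 in Arabidopsis nuclei, 536441 to 6475157 in maize nuclei, 5111739 to 15690915 in sorghum nuclei, 4286818 to 175885808 in Setaria protoplasts and 21038970 to 26778050 in Setaria nuclei, with 46647756 in the sorghum protoplast library. A type with 0 cells could still make up 2.65% of the smallest library, maize nuclei replicate 1, at 3 counts of 113 nuclei. Replicates were compared by a chi-square test of cells per type (scipy 1.17.1). All pairs differed beyond sampling noise except those of maize nuclei replicates 1 and 2, which share 0 barcodes and were kept apart, since the former held only 113 nuclei.

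The replicate in every test is the library. Shares were tested with edgeR 4.0.16 (quasi-likelihood, no trend, robust) on cells per type, with the total number of cells as library size and types of at least 10 cells, in 1 fit for Arabidopsis and 1 fit over all grass groups. Relative UMI content, for types of at least 10 cells in a library, was tested with limma 3.58.1 (robust eBayes). Depth and tissue classes were tested by exact two-sided permutation over libraries, using numpy 2.4.6. P-values were adjusted by Benjamini-Hochberg over the types of 1 contrast, the 10 depth tests or the 5 classes, with a threshold of 0.05. All tests were two-sided. Tests, groups, classes and most alternatives were fixed before the data were examined, as was the rule that all types are named where a table has 20 or fewer. Gene-level comparisons were not made, since the tables used here hold no genes.

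The share test was tested on simulated data in which 4 types changed, 100 simulations per setting. For Arabidopsis protoplasts against nuclei it recovered 11.5% of 2-fold and 82.3% of 4-fold changes. Recovery of 2-fold changes was 16.5% for Setaria and 7% for sorghum protoplasts against nuclei, and 28%, 19.8% and 18.8% for sorghum against maize, Setaria against maize and Setaria against sorghum nuclei. In the same order, recovery of 4-fold changes was 85.8%, 63%, 93.8%, 90.3% and 87.5%. With no change, any type was called in 2% to 6% of simulations. When 4 types did change, 6.67% to 26.3% of calls fell on other types. These simulations gave all libraries the same spread, whereas measured shares spread more in protoplasts than in nuclei. SDs in log2 odds were 0.90 and 0.54 in Arabidopsis and 0.94 and 0.54 in the grasses. How often the share test calls a type under unequal spread was not simulated. The relative UMI test recovered all changes of 1 log2 unit in Arabidopsis, 85.5% in Setaria and 62% in sorghum, and 53%, 14.8% and 9.75% of changes of 0.5 log2 unit, with 3.93% to 17.0% of calls on other types. With no change but protoplasts as variable as measured, that test called any type in 1% of simulations in Arabidopsis, 14% in Setaria, 38% in sorghum and 23% in the interaction of both grasses, against 4%, 6%, 9% and 1% with a spread of its own for each preparation.

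Alternatives included TMM factors, DESeq2 1.42.0, limma on log2 odds with 0.5 added, other filters, a minimum of 1000 UMIs, fits of only the groups compared, chemistry as a covariate, the replicate number as a block and leaving out each library. Added after seeing the data were a minimum of 20000 UMIs for Arabidopsis protoplasts, both treatments of the cells listed 2 times, a split of ctr1, whose barcodes carry 2 suffixes, into 2 libraries, only libraries with barcodes of the version 3 list, leaving out the libraries named ical, and limma fits with a spread of its own for protoplasts and for nuclei, pooled over types, by which libraries were weighted. The version 3 list was inferred from barcodes shared between libraries, by thresholds chosen after the sharing rates were seen.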

Results

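Root tips of 4 plants were profiled on the 10x Chromium platform, either as protoplasts, which are cells freed of their walls by enzymes, or as nuclei released by lysis. The 22 libraries analysed here held 76002 cells or nuclei. The Arabidopsis thaliana set had 6 protoplast libraries and 3 nuclei libraries with 32790 cells, sorted by the authors into 17 named cell types. The grass set had 43212 cells in 19 clusters that carry numbers and no names. It comprised 4 nuclei libraries of maize (Zea mays), 1 protoplast and 3 nuclei libraries of sorghum (Sorghum bicolor), and 3 protoplast and 2 nuclei libraries of Setaria viridis, a small wild grass. The tables list unique molecular identifiers (UMIs, each standing for 1 captured transcript) and detected genes per cell, with no expression of single genes, so the comparisons concern how common each cell type was and how many UMIs it held. Nothing in the labels says whether libraries of a group came from separate plantings, so p-values measure only the spread between libraries, which may be technical.

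Protoplasts in the tables held more UMIs than nuclei. In Arabidopsis the minima of the tables set part of that difference, since protoplast libraries began at 10002 to 15068 UMIs per cell and nuclei at 1150 to 1211. The library medians ran from 16709 to 28379 UMIs per protoplast and from 2320 to 2984.5 UMIs per nucleus, a mean difference of 3.00 on the log2 scale or 7.99-fold. Detected genes differed by 1.42 on the log2 scale (2.67-fold), with medians of 4095.5 to 6107 genes in protoplasts and 1707 to 2046.5 in nuclei. All 6 protoplast libraries lay above all 3 nuclei libraries in genes, as they had to in UMIs, where each protoplast minimum exceeded every nuclei median and a test says nothing. For genes, counted in the same cells, the exact two-sided permutation test gave p = 0.0119, the smallest the 84 splits allow, and an adjusted p of 0.0595 over the 10 depth tests, which did not pass.

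Setaria protoplasts held 3593, 19938 and 22643.5 UMIs at the median in replicates 1, 2 and 3, and Setaria nuclei held 2306 and 2552. The log2 difference was 2.28 for UMIs and 1.19 for genes (exact permutation p = 0.2 for both, where 0.1 is the smallest possible). Without protoplast replicate 1 it was 3.13 for UMIs and 1.74 for genes. Among cells of 2000 to 4000 UMIs, the log2 difference in genes was 0.07 (exact permutation p = 0.7). Median genes in that range were 1349, 1745 and 1710 in protoplast replicates 1, 2 and 3, and 1500 and 1525 in Setaria nuclei. Replicate 1 thus lay below both nuclei libraries and replicates 2 and 3 above both. The single sorghum protoplast library had a median of 9663 UMIs and began at 2735, against medians of 1166.5, 1929 and 1856 in the sorghum nuclei libraries. Maize nuclei had medians of 2589 to 4121.5 UMIs. Minima also differed between species, at 1461 to 1555 UMIs in maize nuclei, 650 to 1318 in sorghum and 993 to 1069 in Setaria. In genes they were 1252 to 1257, 601 to 982 and 802 to 841 in the same order. The Sorgh_Nucl median of 1166.5 UMIs lay below every maize minimum. How far minima set the depth differences between species was not tested. Sorghum nuclei lay below maize nuclei by −1.10 in log2 UMIs and −0.90 in log2 genes (exact permutation p = 0.0286 for both, the smallest possible; adjusted p = 0.0714). Setaria nuclei differed from maize nuclei by −0.51 in log2 UMIs (exact permutation p = 0.133) and −0.57 in log2 genes (p = 0.0667), and from sorghum nuclei by 0.59 and 0.32 (p = 0.2 for both). Among nuclei of 2000 to 4000 UMIs the log2 gene difference was −0.30 between sorghum and maize (exact permutation p = 0.0571), −0.39 between Setaria and maize (p = 0.0667) and −0.09 between Setaria and sorghum, the last of the opposite sign. Depth was not equal within that range, where library medians were 2488 to 3161 UMIs in maize, 2248 to 2561.5 in sorghum and 2425 to 2505 in Setaria nuclei, and 2874 to 3178 in Setaria protoplasts.

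**Figure D1:**
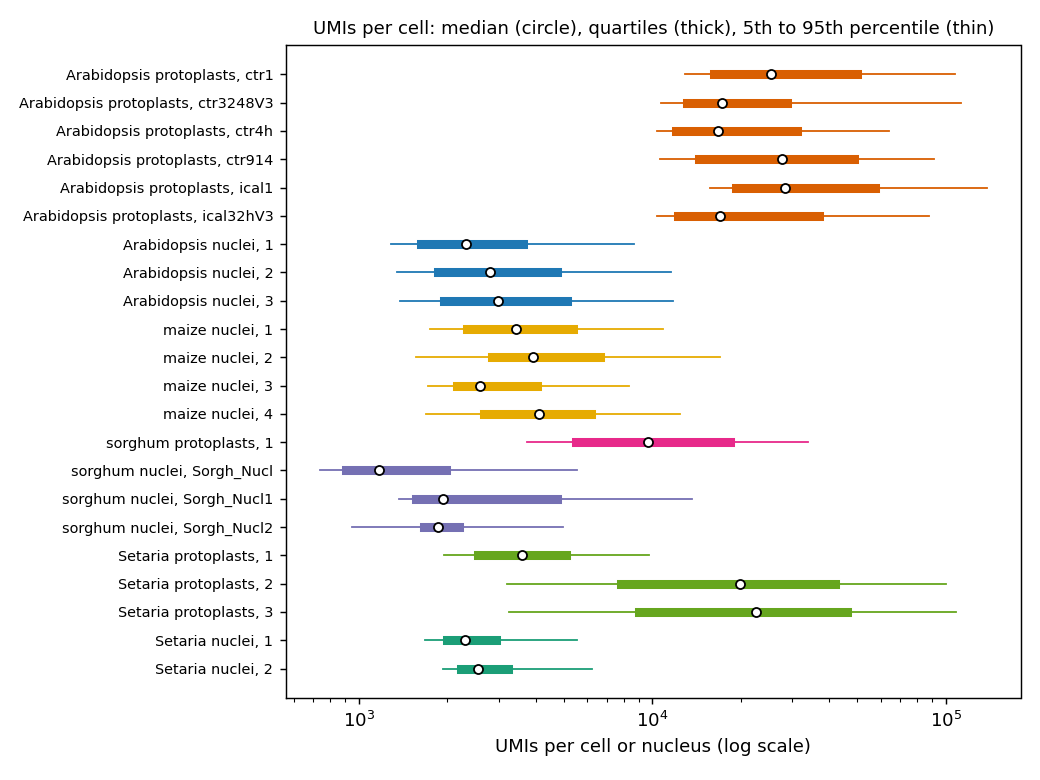
UMIs per cell or nucleus in each of the 22 libraries, on a log scale; circles are medians, thick bars quartiles and thin lines the 5th to 95th percentile. Medians of Arabidopsis protoplasts lie at 16709 to 28379 and those of Arabidopsis nuclei at 2320 to 2984.5, and Setaria protoplast replicate 1, at 3593, lies far below the other 2.

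The series combined cells and nuclei of the same tissue, and the first comparison asks which Arabidopsis cell types each preparation recovered. Of the 5 root cap types, 2 made up more of the protoplasts. The lateral root cap (6_LRC), which sheathes the flanks of the tip, took 9.94% ± 3.56 of protoplasts (SD, n = 6) and 1.34% ± 0.446 of nuclei (SD, n = 3), a log2 fold of 2.89 (SE 0.46) or 7.40-fold. The columella (14_Columella), the gravity-sensing centre of the cap, took 6.32% ± 1.63 and 1.44% ± 0.543, a log2 fold of 2.13 (SE 0.40). Hairless epidermal cells (5_Atrichoblast) took 8.17% ± 3.10 and 3.76% ± 0.359 (log2 fold 1.12, SE 0.37), and the type named 16_Undertermided 4.39% ± 2.25 and 1.22% ± 0.505 (1.84, SE 0.58). Lower in protoplasts were 11_18_Endocortex, at 2.93% ± 1.21 against 11.0% ± 2.21 (−1.91, SE 0.40), and 4_To_determined, at 2.11% ± 1.02 against 11.7% ± 0.777 (−2.48, SE 0.40).

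These were the 6 of 17 types called by edgeR's quasi-likelihood test, with adjusted p of 0.000705 for 6_LRC and 4_To_determined, 0.00139 for 14_Columella, 0.00286 for 11_18_Endocortex, 0.0321 for 16_Undertermided and 0.0352 for 5_Atrichoblast. Shares of 6_LRC, 14_Columella and 5_Atrichoblast in 6 of 6 protoplast libraries, and of 16_Undertermided in 5 of 6, lay above all nuclei libraries. Those of 11_18_Endocortex and 4_To_determined lay below all nuclei libraries in 6 of 6. Protoplast libraries began at 10002 to 15068 UMIs per cell and nuclei at 1150 to 1211. When protoplasts under 20000 UMIs were left out, 6_LRC fell to a log2 fold of 1.07 (SE 0.73, edgeR adjusted p = 0.269) and 14_Columella to 1.11 (SE 0.68, adjusted p = 0.225), and neither passed. The call of 16_Undertermided was lost without ctr1, ical1 or ical32hV3 or any of the 3 nuclei replicates (edgeR adjusted p 0.0510 to 0.119), and that of 5_Atrichoblast without ctr1, ctr4h, ctr914 or ical1 or any nuclei replicate (0.0528 to 0.141). Neither passed by exact permutation of the shares (adjusted p = 0.202 and 0.101), and 16_Undertermided did not pass without both libraries named ical (edgeR adjusted p = 0.113). By the labels, preparation and chemistry version coincide in Arabidopsis. Among the 4 protoplast libraries whose barcodes match the chemistry of the nuclei, 6_LRC, 14_Columella, 11_18_Endocortex and 4_To_determined were called and the other 2 types were not (edgeR adjusted p = 0.0970 for both), with log2 folds of 1.62 (SE 0.65) for 16_Undertermided and 1.15 (SE 0.45) for 5_Atrichoblast.

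The other 11 types did not pass. Other root cap types had log2 folds of 0.92 (0_Young_Columella, SE 0.47), 0.44 (7_Young_LRC, SE 0.54) and 0.33 (9_Columella_LRC_Indertermined, SE 0.27). Root-hair cells (13_Trichoblast) had 0.66 (SE 0.39) and 2_12_15_19_Initials_Epidermis −0.03 (SE 0.30). Below 0 lay 17_Stele (−0.95, SE 0.62), 21_endodermis (−0.63, SE 0.70), 1_3_G2MphaseCells (−0.61, SE 0.26), 20_Cortex (−0.56, SE 0.42), 8_Initials_QC (−0.45, SE 0.33) and 10_Pericycle (−0.40, SE 0.99). Although 1_3_G2MphaseCells, cells named for late phases of the division cycle, made up 10.8% ± 2.23 of protoplasts and 16.5% ± 0.413 of nuclei and lay below all nuclei libraries in 6 of 6, its edgeR adjusted p was 0.0998 (0.0322 by limma on log2 odds with a spread of its own for each preparation). The pericycle, the outer layer of the stele, ranged from 0.531% to 12.5% among protoplast libraries and from 4.04% to 7.81% among nuclei libraries.

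**Figure D2:**
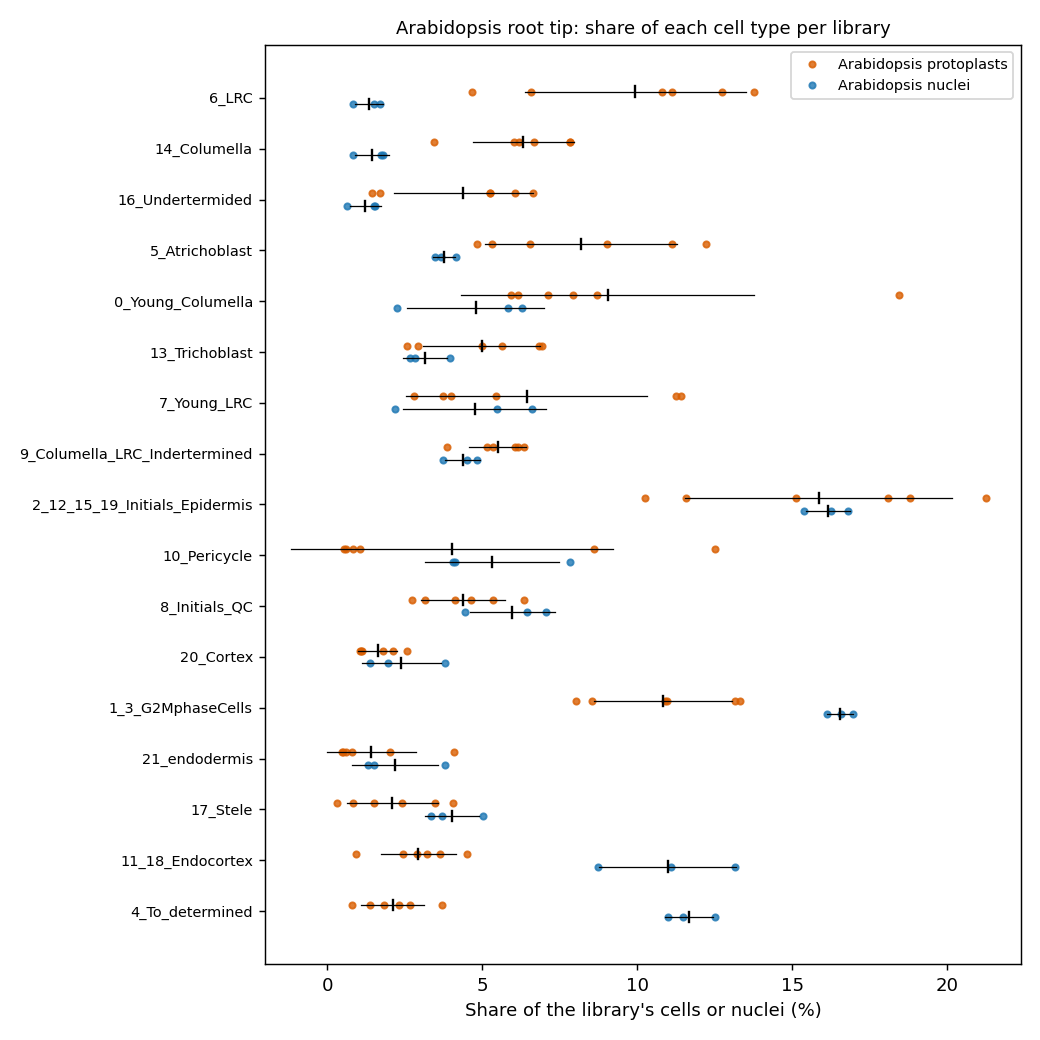
Share of each annotated Arabidopsis cell type in percent, 1 point per library, for 6 protoplast and 3 nuclei libraries; vertical ticks are group means and horizontal lines the SD. The 6_LRC points of protoplasts lie at 4.68% to 13.8% and those of nuclei at 0.836% to 1.69%.

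Grouped by tissue, the root cap took 37.2% ± 11.0 of protoplasts and 16.7% ± 5.98 of nuclei (exact permutation adjusted p = 0.0397 over 5 classes, n = 6 and 3). Ground tissue (endocortex, cortex and endodermis) took 5.97% ± 2.05 and 15.5% ± 4.75 (exact permutation adjusted p = 0.0298). Meristem names (1_3_G2MphaseCells and 8_Initials_QC) took 15.2% ± 2.27 and 22.5% ± 1.31 (exact permutation adjusted p = 0.0298). Epidermis, in which 2_12_15_19_Initials_Epidermis was counted, took 29.0% ± 6.80 and 23.0% ± 0.596 (exact permutation adjusted p = 0.208). Stele took 6.11% ± 6.48 and 9.33% ± 3.03 (exact permutation adjusted p = 0.405), and neither of these 2 passed the threshold. The 2 names in no class, 16_Undertermided and 4_To_determined, together took 6.50% ± 2.52 and 12.9% ± 1.02. The root cap call was lost without ctr1, ctr4h, ical1, ical32hV3 or any nuclei replicate (exact permutation adjusted p 0.0595 to 0.179). The ground tissue and meristem calls were lost without any nuclei replicate (0.0595 to 0.0893). Fewer libraries raise the smallest p these exact tests allow, so a lost call need not mean a smaller difference.

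Within each library, UMIs were also compared between cell types, as the type's median log2 UMIs minus the median over types. Relative to other types, epidermal cells held more UMIs in protoplasts than in nuclei. Protoplast libraries began at 10002 to 15068 UMIs per cell and nuclei at 1150 to 1211, so low values were cut differently. Types also spread less in nuclei (group means −0.56 to 0.47) than in protoplasts (−0.72 to 1.37). How far minima and spread set the differences was not tested. Among types relatively higher in protoplasts, the largest differences were those of 2_12_15_19_Initials_Epidermis (0.98, SE 0.14) and 13_Trichoblast (0.94, SE 0.15). These were followed by 11_18_Endocortex (0.79, SE 0.16), 4_To_determined (0.46, SE 0.12) and 5_Atrichoblast (0.46, SE 0.14). Of the 5 root cap types, 3 held relatively fewer: 6_LRC −0.85 (SE 0.16), 7_Young_LRC −0.52 (SE 0.15) and 0_Young_Columella −0.50 (SE 0.13). The values of 14_Columella (−0.37, SE 0.16) and 9_Columella_LRC_Indertermined (−0.17, SE 0.12) did not pass (limma adjusted p = 0.0771 and 0.280), although the former passed with a spread of its own for each preparation (0.0284). limma called these 8 of 17 types, with adjusted p from 9.3e-05 to 0.0132. Measured against the median over all cells of the library, 5 were called, 4 higher and 1 lower, against 5 higher and 3 lower, and 7_Young_LRC, 0_Young_Columella and 4_To_determined did not pass (limma adjusted p 0.0629 to 0.0961). The call of 7_Young_LRC was also lost without nuclei replicate 1 (limma adjusted p = 0.0782) and that of 5_Atrichoblast without nuclei replicate 2 (0.0608).

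The same question was asked in Setaria, where clusters are known by number. Clusters 2 and 5 were the most depleted from protoplasts. Cluster 2 took 1.00% ± 0.686 of protoplasts (SD, n = 3) and 10.8% ± 2.41 of nuclei (SD, n = 2), a log2 fold of −3.58 (SE 0.54), and cluster 5 took 1.07% ± 0.659 and 10.8% ± 0.263 (−3.22, SE 0.54). Clusters 4 (log2 fold 1.88, SE 0.52), 18 (1.42, SE 0.55) and 6 (1.38, SE 0.52) were higher in protoplasts. In cluster 4 this was 13.7% ± 4.49 against 3.76% ± 0.454.

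All 3 Setaria protoplast libraries lay beyond both nuclei libraries in each of these 5 of 19 clusters. They did so too in clusters not called, such as 1 (log2 fold 0.31, SE 0.50) and 12 (0.46, SE 0.50). Such separation is therefore not particular to the 5. The edgeR adjusted p was 6.7e-08 and 4.4e-07 for clusters 2 and 5, 0.00348 for cluster 4 and 0.0413 for clusters 6 and 18. The calls of clusters 4, 6 and 18 were lost without either nuclei replicate, which left 2 calls (edgeR adjusted p 0.0746 to 0.267), and when only Setaria libraries were fitted (0.0545 to 0.190). Cluster 6 was also lost without protoplast replicate 2 (0.112) or 3 (0.0773), and cluster 18 without replicate 3 (0.192). By limma on log2 odds neither passed (adjusted p = 0.0892 and 0.128). With the replicate number as a block, clusters 4, 6 and 18 did not pass. Without protoplast replicate 1, the library with the lowest UMIs and the only Setaria library labelled with the older chemistry, 12 clusters were called, 6 higher and 6 lower. With the labelled chemistry as a covariate 12 were also called, but that covariate rests on the same library and is not a second result.

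In sorghum, clusters 2 and 5 were again the lowest in protoplasts. Cluster 2 held 0.426% of the single protoplast library (15 cells; 95% Wilson interval 0.258% to 0.701%, counting error only) and 12.7% ± 0.588 of nuclei (SD, n = 3), a log2 fold of −4.88 (SE 0.89). Cluster 5 held 0.454% (0.280% to 0.736%) and 7.88% ± 3.88 (−4.10, SE 0.88), and cluster 13 held 0.851% and 4.37% ± 0.267 (−2.36, SE 0.77). Clusters 18 (log2 fold 2.50, SE 0.61), 17 (2.25, SE 0.59) and 16 (2.09, SE 0.59) were higher in protoplasts, each near 5% of protoplasts and at 0.964% ± 0.510, 1.05% ± 0.211 and 1.26% ± 0.174 of nuclei.

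edgeR called these 6 of 19 clusters with adjusted p from 9.3e-06 to 0.00951, on the assumption that the lone protoplast library varies like the other groups. Protoplast libraries of Setaria varied more than grass nuclei, however, with SDs of 0.94 and 0.54 in log2 odds of share. With a spread of its own for each preparation (limma on log2 odds), clusters 2 and 5 passed and clusters 13, 16 and 17 (adjusted p = 0.0752 for each) and 18 (0.154) did not. Fitted on sorghum libraries alone, 11 clusters were called. With the labelled chemistry as a covariate, cluster 13 had a log2 fold of −0.49 (SE 0.83), cluster 5 of −1.87 (SE 1.36) and cluster 17 of 1.42 (SE 0.60), and none of these passed. That covariate is estimated from Setaria protoplast replicate 1 against replicates 2 and 3 alone. Barcodes of the sorghum protoplast library match the version 3 list (63 shared, 49.6 expected), as in its nuclei. These values therefore do not show an effect of chemistry in sorghum.

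The fold from nuclei to protoplasts was then compared between Setaria and sorghum. No cluster differed between these grasses at an adjusted p under 0.05 in edgeR's interaction test, with 1 at an unadjusted p under 0.05 (cluster 15, 1.75, SE 0.87), and DESeq2 and limma also called 0. The interaction ranged from −1.45 (cluster 7, SE 0.81) to 1.75, with SEs of 0.76 to 0.92, so that only large differences were detectable. Without Setaria protoplast replicate 1, 6 clusters were called.

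**Figure D3:**
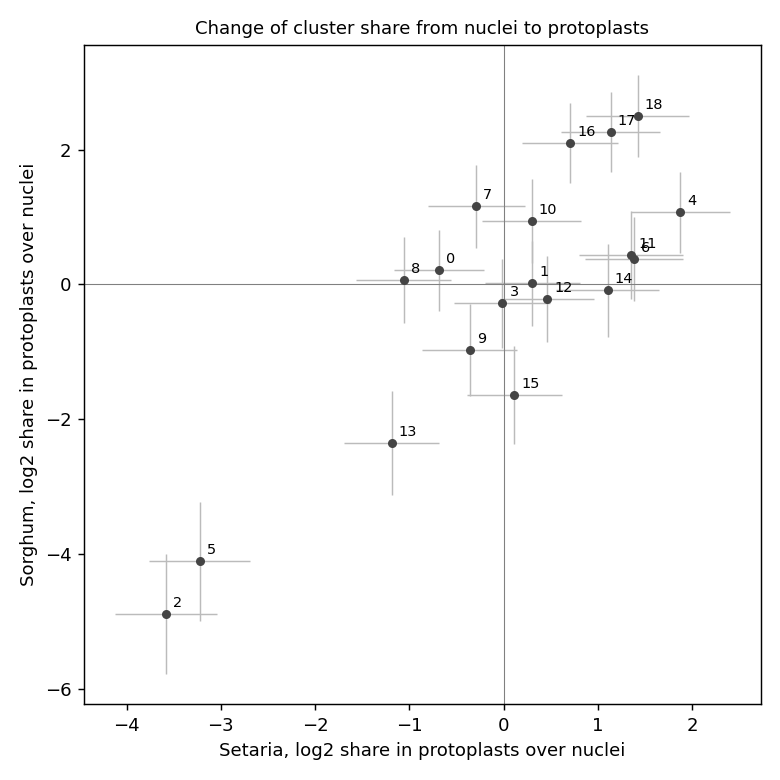
Log2 fold of the share of each of the 19 grass clusters in protoplasts over nuclei, Setaria on the horizontal and sorghum on the vertical axis, with SE bars; numbers name clusters. Clusters 2 and 5 lie at the lower left, at −3.58 and −3.22 in Setaria and −4.88 and −4.10 in sorghum.

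UMIs of clusters relative to the rest of their library also shifted with the preparation. Minima differed here too, at 1611 to 2505 UMIs in Setaria protoplasts and 993 to 1069 in Setaria nuclei. In sorghum they were 2735 in protoplasts and 650 to 1318 in nuclei. Their effect on these values was not tested. In Setaria protoplasts cluster 13 held relatively more than in nuclei (1.24, SE 0.15), and clusters 5 (−1.88, SE 0.30) and 2 (−1.71, SE 0.49) held relatively fewer. Clusters 13 and 5 had at least 10 cells in only 2 of the 3 protoplast libraries, as replicate 1 held 7 and 3 cells of them. With the replicate number as a block, none of the 3 Setaria calls passed (limma adjusted p = 0.0671 for clusters 13 and 5). In sorghum, clusters 15 (1.61, SE 0.35), 11 (1.46, SE 0.28), 8 (1.45, SE 0.26), 10 (1.42, SE 0.22) and 12 (0.63, SE 0.19) held relatively more, and clusters 16 (−1.50, SE 0.37) and 14 (−1.27, SE 0.40) relatively fewer. limma's interaction test between the grasses called 9 of 19 clusters, 7 lower and 2 higher in Setaria, from −1.90 in cluster 15 (SE 0.45) to 1.41 in cluster 14 (SE 0.51; limma adjusted p from 0.00393 to 0.0435). The sorghum and interaction values rest on 1 sorghum protoplast library, assumed to vary like the other groups, but Setaria protoplast libraries varied more than grass nuclei (SD 0.50 and 0.25). With a spread of its own for each preparation, limma called only sorghum clusters 8, 10 and 11 (adjusted p 0.00946 to 0.0373) and, in the interaction, only cluster 13 (1.39, SE 0.30, adjusted p = 0.0245).

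limma's adjusted p ranged from 0.000373 to 0.0320 over the 3 Setaria calls and from 0.00141 to 0.0289 over the 7 sorghum calls. Against the median over all cells, 4 Setaria clusters were called, 2 higher and 2 lower (1 higher and 2 lower as reported), 9 sorghum clusters, 4 higher and 5 lower (5 and 2 as reported), and 3 in the interaction test, 2 higher and 1 lower. Without Setaria protoplast replicate 1 the Setaria calls rose to 10 and the interaction calls to 13. Without Setaria nuclei replicate 1 or 2 or Sorgh_Nucl1 the interaction calls fell to 3, without Sorgh_Nucl or Setaria protoplast replicate 3 they were 6, and without Sorgh_Nucl2 they were 12. Setaria cluster 2 was not called without protoplast replicate 2 or 3 or either nuclei replicate (limma adjusted p 0.0831 to 0.166), and sorghum clusters 12 and 14 not without Sorgh_Nucl1 (0.0698). Sorghum cluster 12 was also lost with at least 5 or 30 cells per type and library (limma adjusted p = 0.0870 and 0.0708) and against the median over all cells (0.299), and passed in 3 of 8 alternatives.

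The species were compared within nuclei. Cluster 0 was the largest in maize, at 17.4% ± 5.12 (SD, n = 4), against 12.3% ± 1.28 in sorghum (n = 3) and 11.6% ± 1.02 in Setaria (n = 2), and cluster 2 took 11.4% ± 2.08, 12.7% ± 0.588 and 10.8% ± 2.41. Cluster 3 took 4.09% ± 2.72 of maize, 5.08% ± 1.19 of sorghum and 8.12% ± 0.418 of Setaria nuclei, a log2 fold of 1.01 (SE 0.50) for Setaria over maize. Cluster 9 took 8.49% ± 2.99, 6.63% ± 1.00 and 4.41% ± 0.508 (−0.89, SE 0.51). None of these differences in share passed the test.

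edgeR called 0 of 19 clusters in each of the 3 species pairs, with 0 at an unadjusted p under 0.05 for sorghum and maize, 1 for Setaria and maize (cluster 3, adjusted p = 0.474) and 0 for Setaria and sorghum, and DESeq2 and limma also called 0. Log2 folds ranged from −0.57 to 0.74, from −0.89 to 1.01 and from −0.95 to 0.69, with SEs of 0.42 to 0.61. In relative UMIs, limma called 0 clusters in each pair, with 2, 1 and 0 at an unadjusted p under 0.05. Per the labels, root tips were taken at 0.5 cm after 7 days of growth in maize and sorghum, and at 0.2 cm after 15 days in Setaria. Species, length of tip and growth time therefore cannot be separated for Setaria, nor species and labelled chemistry for maize. With the labelled chemistry as a covariate, which Setaria protoplast replicate 1 alone informs, 10, 7 and 0 clusters were called. With only the groups compared, 2 were called for Setaria and sorghum, and without maize replicate 3, 1 for Setaria and maize. In relative UMIs, 1 cluster was called for sorghum and maize without Sorgh_Nucl2, and 1 with a spread of its own for each preparation (cluster 14, 0.86, SE 0.20).

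**Figure D4:**
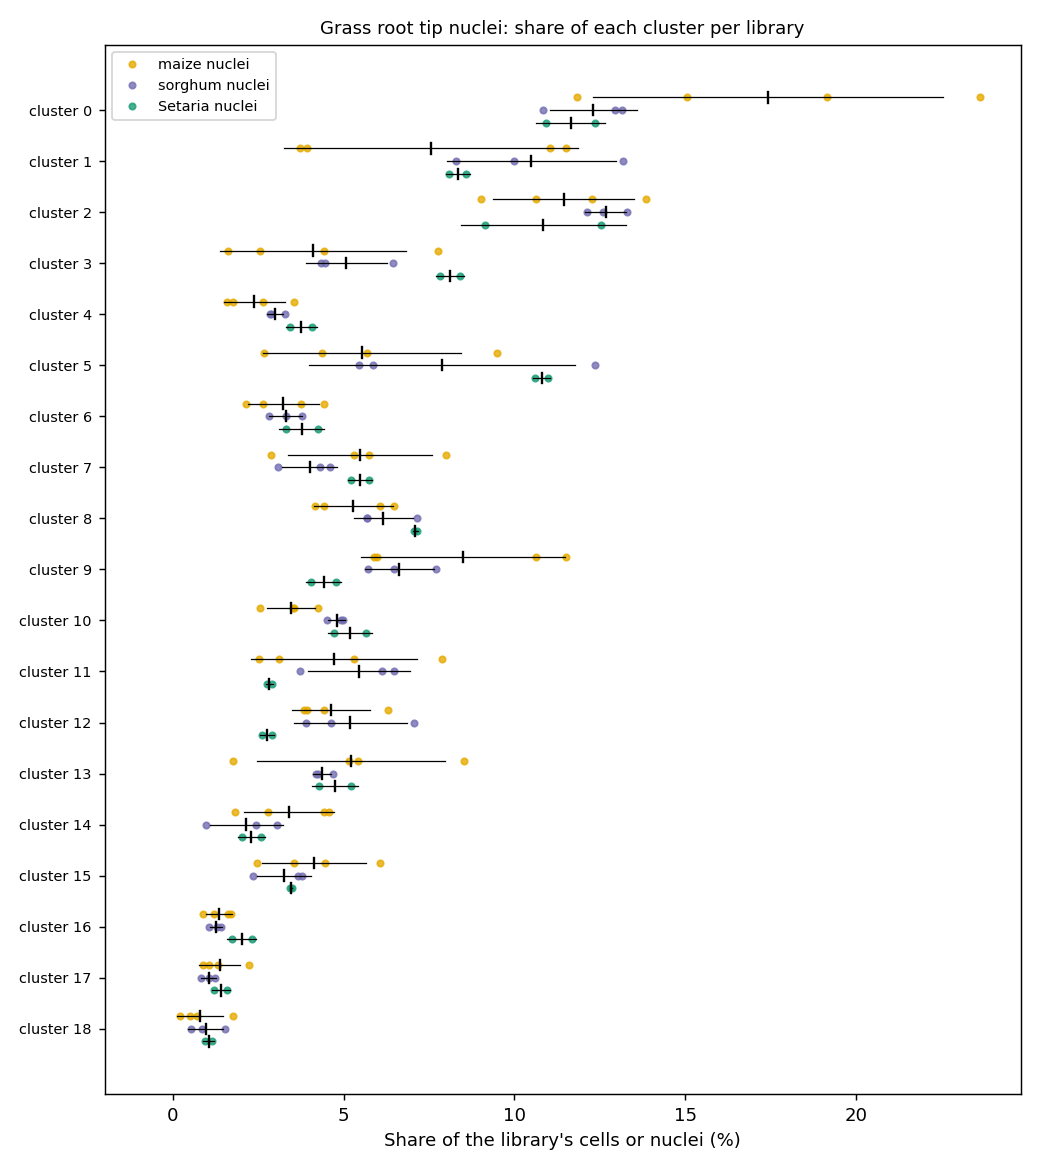
Share of each of the 19 grass clusters among nuclei in percent, 1 point per library, for 4 maize, 3 sorghum and 2 Setaria libraries; vertical ticks are group means and horizontal lines the SD. In cluster 3 the Setaria mean is 8.12% and the maize mean 4.09%, with maize libraries spread from 1.62% to 7.77%.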

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

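For results in this part, tests chosen only after the result was seen were those with a minimum of 20000 UMIs, those with version 3 barcodes alone, both barcode tests, the other listing of ical1 and the fit with a spread of its own for each preparation.

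The Arabidopsis protoplast library ctr3248V3 stood apart in 3 measures, with a large gap to the nearest of the other 5 libraries. Its share of 0_Young_Columella was 18.5%, against 5.94% to 8.69%. Its relative UMI content was 0.48 for 17_Stele, against −0.20 to 0, and −0.97 for 7_Young_LRC, against −0.74 to −0.62. In all, 69 sets of values were tested in this way and chance alone marks about 1 in 20, so a count of 3 is no more than chance gives. All 3 fell in 1 library, however, and the sets are not independent, so the count does not show that ctr3248V3 is ordinary. Its root cap share was 56.3%, against 22.4% to 39.2% in the other 5.

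For the change in relative UMI content from nuclei to protoplasts, 9 clusters were called as different between Setaria and sorghum by limma's interaction test, in which sorghum protoplasts are 1 library assumed to vary like the other groups. Setaria minus sorghum it was −1.90 in cluster 15, −1.61 in cluster 5, −1.52 in cluster 11, −1.51 in cluster 7, −1.09 in cluster 8, −0.97 in cluster 10, −0.90 in cluster 17, 1.39 in cluster 13 and 1.41 in cluster 14. Only cluster 13 passed in all 13 alternatives. Against the median over all cells 3 clusters were called, and with a spread of its own for each preparation only cluster 13 was.

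In the Arabidopsis library ical1, whose cells were each listed 2 times, the other listing gave another cell type name to 45 of 1085 cells, 4.15% (exact 95% interval 3.04% to 5.51%). No Arabidopsis share call changed when the names of the other listing were used.

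The first pattern weighed is that 6_LRC, 14_Columella, 5_Atrichoblast and 16_Undertermided were higher, and 11_18_Endocortex and 4_To_determined lower, in Arabidopsis protoplasts than in nuclei. If the high UMI minimum of protoplasts had removed the lower names, a minimum of 20000 would remove more. Their summed share instead rose to 1.33 times its value in the median library (0.999 to 2.11). The summed share of the names higher in protoplasts fell to 0.785 times in the median library, and fell in 6 of 6. Neither sum thus moved as a protoplast minimum would need. The calls of 6_LRC and 14_Columella nevertheless ended at that minimum, from 2.89 (SE 0.46) to 1.07 (SE 0.73) and from 2.13 (SE 0.40) to 1.11 (SE 0.68). The folds fell and the errors grew, so part of that excess lies in protoplasts of fewer UMIs. Each sum also joins types of unlike UMI content. Mean relative log2 UMIs in protoplasts were 0.72 for 5_Atrichoblast and −0.71 for 6_LRC among the higher names. Among the lower names they were 0.82 for 11_18_Endocortex and −0.10 for 4_To_determined. For single types an effect of the protoplast minimum therefore stays open. Among the 4 protoplast libraries with barcodes of the version 3 list, as in nuclei, the median absolute log2 fold was 1.03 times that of all libraries (4 of the 6 types called). This argues against the chemistry as far as the inferred lists hold. Of the 84 splits of the 9 libraries only the real one (1 of 84) gave 6 called types (highest other 5). That is the smallest fraction 84 splits allow, so chance is unlikely for the number of calls but not excluded. The minimum of 1001 genes applied to nuclei was not tested and stays open, as does a real difference in how the preparations release these types.

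The second pattern is the pericycle share of Arabidopsis protoplast libraries, which was 12.5% in ctr4h, 8.60% in ctr914, 1.06% in ctr1, 0.829% in ical1, 0.602% in ical32hV3 and 0.531% in ctr3248V3. Chemistry does not account for it, as libraries with version 3 barcodes alone differed 23.5-fold, and neither does the UMI minimum, as the ratio was 16.7 among cells of at least 20000 UMIs. No biological explanation was tested, since the labels give these libraries no differing treatment, age or tip length, and the meaning of their names stays open.

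The third pattern is in the barcodes, where 9 libraries labelled version 2 shared 323 barcodes with libraries labelled version 3, and 283 were expected if all came from the same list, a ratio of 1.14 (95% interval 1.02 to 1.27). These 9, picked by their own sharing rates, are the 4 maize nuclei libraries, the sorghum protoplast library and the Arabidopsis libraries ctr3248V3, ctr4h, ctr914 and ical32hV3, whereas ctr1 and Setaria protoplast replicate 1 together shared 2 and 60.1 were expected (ratio 0.0333). Cells carried over between libraries would pile up in some pairs. Among the 90 pairs with at least 3 shared barcodes expected, the highest ratio was 2.04. No pair with a maize library had 3 expected, so carry-over was not tested for the 4 maize nuclei libraries. A candidate explanation is that the chemistry label is wrong for these 9 libraries. For ical1, with 4 shared and 15.3 expected, the list could not be resolved, and no biological explanation was tested.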

How the results depend on the processing

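Among alternatives in this part, those chosen only after the result was seen were the 6 added for Arabidopsis shares (the 20000 UMI minimum, the 2 treatments of repeated listings, the split library, version 3 barcodes alone and no ical libraries) and the limma fits with a spread of its own for each preparation. Of 44 type calls followed over the alternatives, 0 reversed direction (edgeR and limma), 13 passed in all that were followed, and 471 of 580 values passed. Single types were followed through the fits with a spread of its own only in contrasts that include sorghum protoplasts. The Arabidopsis and Setaria calls that passed in all were therefore not followed through those fits. Among shares, 11_18_Endocortex and 4_To_determined passed in all 22 alternatives, Setaria clusters 2 and 5 in all 14 and sorghum cluster 2 in all 12. The no-filter and 100-cell filters removed no type, and the 1000 UMI minimum moved nothing in Arabidopsis. These settings say nothing about stability, although they are counted among the 580 values.

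Setaria share calls (5) became 3 with limma, 2 with only the groups compared, 12 with chemistry as a covariate and 2 to 12 leaving out 1 library (12 without protoplast replicate 1, 2 without either nuclei replicate). Sorghum share calls (6) became 11 with only the groups compared. With a spread of its own for each preparation, share calls became 3 in Setaria and 2 in sorghum, and relative UMI calls 3 in sorghum (7 as reported), 1 in the interaction (9) and 1 for sorghum and maize (0). Species calls of 0 (edgeR; 0, 1 and 0 unadjusted; 0 by DESeq2 and limma) became 10 for sorghum and maize and 7 for Setaria and maize with the chemistry covariate, 2 for Setaria and sorghum with only the groups compared, and 0 to 1 for Setaria and maize leaving out 1 library (1 without maize replicate 3). The share interaction (edgeR 0; 1 unadjusted; 0 by DESeq2 and limma) became 1 with the chemistry covariate and 0 to 6 leaving out 1 library (6 without Setaria protoplast replicate 1). That covariate rests on Setaria protoplast replicate 1 alone, whose barcodes match its label, and on labels that barcodes put in doubt for 9 other libraries.

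Relative UMI calls against the median over all cells became 5 in Arabidopsis (8 as reported) and 3 in the interaction (9). Leaving out 1 library they were 2 to 10 in Setaria (10 without protoplast replicate 1), 3 to 13 in the interaction (13 without Setaria protoplast replicate 1, 3 without Sorgh_Nucl1 or either Setaria nuclei replicate) and 0 to 1 for sorghum and maize (1 without Sorgh_Nucl2), which also had 1 with at least 30 cells (limma 0 as reported; 2 unadjusted). The gene difference between Setaria and sorghum nuclei was −0.0903 on the log2 scale at 2000 to 4000 UMIs. Over all nuclei it was 0.185 to 0.422 leaving out 1 library, and the UMI difference of that pair 0.358 to 0.721. Leaving out 1 library, class differences were 16.7 to 23.5 points for root cap, −11.7 to −6.99 for ground tissue and −8.07 to −6.51 for meristem, with calls lost without the libraries named in the report. For the classes not called they were 3.93 to 7.86 for epidermis and −5.19 to −1.48 for stele. Fewer libraries raise the smallest p these exact tests allow. For all other changes the cause was not tested.

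With the replicate number as a block, Setaria shares gave 2 calls (clusters 4, 6 and 18 were lost) and Setaria relative UMIs 0 (limma; 8 unadjusted without the block), UMI and gene differences of Setaria protoplasts and nuclei were 2.12 and 1.10, and those of Setaria and maize nuclei −0.27 and −0.45. It changed no other call. The numbers give too few pairs to test pairing (correlations −0.46 and −0.31), so they are only numbers. No paired analysis was possible because libraries carry no replicate number for Arabidopsis protoplasts and sorghum nuclei. Not run were exact permutation of shares in the smaller designs, which cannot fall under 0.05, and matched UMIs in Arabidopsis, where protoplasts begin above 4000 UMIs.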

Other observations

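Of the tests in this part, those chosen only after the result was seen were the correlations, while the splits of libraries were planned.

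Across the 19 clusters the log2 folds of share from nuclei to protoplasts correlated between Setaria and sorghum, with Spearman's rho = 0.702 (permutation p = 0.00126) and Pearson's r = 0.845 (permutation p = 6e-05), and 13 of 19 had the same sign. Clusters 2 and 5 were the lowest in both grasses. The sorghum folds rest on 1 protoplast library, and without Setaria protoplast replicate 1 edgeR's interaction test called 6 clusters as different between the grasses. Without the 2 clusters farthest from the Setaria median r was 0.582. The correlation is across clusters, whose shares sum to 100% and which are not independent replicates, so the p-values may be too small. A shared loss of the same cells during wall digestion is a hypothesis that was not tested. Nor was a minimum of UMIs per protoplast tested in the grasses. Setaria protoplast replicates 2 and 3 began at 2505 and 2501 UMIs, and the sorghum protoplast library at 2735. Mean relative log2 UMIs of clusters 2 and 5 were −1.79 and −1.82 in Setaria protoplasts, and −0.58 and −0.41 in sorghum protoplasts. Both explanations stay open.

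It was also asked whether types with relatively fewer UMIs in protoplasts take a larger share of them. Spearman's rho across types was −0.446 in Arabidopsis (permutation p = 0.0733, adjusted p = 0.22 over 3 relations; r = −0.505, adjusted p = 0.115), −0.0789 in Setaria (adjusted p = 0.997; r = 0.349, adjusted p = 0.217) and −0.00175 in sorghum (adjusted p = 0.997; r = −0.0116, adjusted p = 0.963). None passed. Without the 2 types farthest from the median, r was −0.387, −0.563 and 0.0379, so the Setaria value, which turned sign, rests on 2 clusters.

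The relative UMI calls in Arabidopsis were also set against other splits of the libraries. Of the 84 splits, only the real one (1 of 84) gave 8 calls, with 2 in the highest other. That is the smallest fraction 84 splits allow, so chance is unlikely for their number but not excluded. For sorghum and maize nuclei, 35 of 35 splits gave at least as many share calls as the real 0 (edgeR; 0 unadjusted; 0 by DESeq2 and limma; highest other 0), and 35 of 35 gave at least as many relative UMI calls as the real 0 (limma; 2 unadjusted; highest other 1). With a real count of 0 every split gives at least as many, so these comparisons say nothing about chance.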
